A study of Drosophila melanogaster with 24 samples.

How the data were processed

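The 24 samples were grouped by the tissue and sex in their titles into 6 groups of 4. Dye came from the label field and the RIL number (RIL 58 or RIL 89, called the line number from here on) from the description field. Total RNA was extracted and its messenger fraction was amplified by reverse transcription and in vitro transcription before labelling, per the labels.

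Each sample had 1 scanner text file of 22575 spots. Its spot and background brightness columns are linear intensity values of 1 dye channel with no normalisation, per the file headers. The quantification also gives each spot a quality score, per the file headers, whose values are not explained there. The program that quantified the images is not given in the sources used here. The series also holds a deposited value table with 1 column per sample. Set against the scanner files, the deposited values are the natural log of mean signal minus mean background, differing by at most 9e-08, with blanks where that difference is not above 0 and no normalisation between samples. Their column medians ran from 2.78 to 5.00. All of its columns belong to the 24 samples.

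From the scanner files, background was corrected with normexp and an offset of 50 on mean signal and mean background, values were taken to log2, and the 24 samples were quantile normalised together. No spot was left out, because the files name no controls, and spots were tested singly, because the files name no probes. The tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

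A single limma model was fitted to all samples, with 6 group means, dye and line number as terms, and moderated tests with a variance trend. The quality scores were identical at every spot for 12 pairs of samples, each of a Cy3 and a Cy5 sample. These pairs were treated as shared arrays and entered as a random block, with an estimated correlation of 0.66 and 16 residual degrees of freedom. Contrasts were the difference between the sexes in each tissue, the differences between tissues averaged over the sexes, the line number, and a joint F-test of the difference of the sex effects between tissues. Calls have a Benjamini-Hochberg adjusted p under 0.05 over the 22575 spots. All tests were two-sided. The groups, the other terms of the model, the rule for the spots to be named and the other settings to be tried were fixed before the data were examined. In the plan, the array block depended on the files naming shared arrays. Here the pairs were inferred from the quality scores, so the block in the planned fit was settled from the data. Without it the sex counts in the antenna, first legs and proboscis were 3, 7 and 6, against 25, 27 and 1219 with it.

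The rule for named features took, in each sex contrast, the 10 largest rises and the 10 largest falls among called spots whose 4 male and 4 female values did not overlap, in each tissue the 12 spots with the largest smaller difference from the other tissues, and for the interaction the 8 smallest p-values. Because the files do not pair spots with genes, at most the leading 2 per direction are given by number and the rest as ranges. For the same reason none of the 33 gene lists fixed beforehand could be tested, the genes that the rule always names could not be looked up, and means over the probes of a gene were replaced by single spots.

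After the data were examined, the arrays were divided at the widest gap in the correlation between their channels (0.139, against 0.0760 for the next gap) into a set of 8 and a set of 4. The added fit gives each set its own dye effect, in place of 1 for all, with an array correlation of 0.552 and 14 residual degrees of freedom. Fits on each set alone, without spots that carry a quality mark on any array (1090 spots), with loess within arrays, and with replicates 1 and 2 against replicates 3 and 4 in place of the line number were added at the same stage. A further added model held the line number in females, the line number in males and the replicate numbers in males as separate terms, with 12 residual degrees of freedom.

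The other settings fixed beforehand were no background correction, scaling to 1 median, cyclic loess, the deposited value table, leaving out the dimmest 25% of spots, no dye or line term, no variance trend, sample quality weights, the replicate number as a block, the array as a fixed block or as none, each sample left out in turn, and each tissue fitted alone. Of the fits to 1 tissue alone, only that of the proboscis was obtained. The planned fit was tested on simulated data for the antenna comparison, in which 200 of 22575 spots were changed. It recovered 63% of 100 spots changed by 0.5 and 96% of 100 spots changed by 1 on the log2 scale, none with the wrong direction, and 7.56% of its 172 calls were false. The simulated data held 1 dye effect for all arrays and an array correlation of 0.5. They therefore do not show the share of false calls where the dye effect differs between array sets.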

Results

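Gene expression was measured in 3 sensory body parts of adult fruit flies (Drosophila melanogaster), collected from each sex 1 to 2 hours after eclosion, the emergence of the adult from the pupal case. The antenna, taken as its outer segment with the arista, is the main olfactory organ of the fly. The first legs, taken from the distal tibia outward, carry taste bristles and, in males, the sex comb. The proboscis is the mouthpart that bears the taste organs of the labellum. Each of the 6 groups of tissue and sex held 4 samples, 24 in all.

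Each sample was 1 dye channel of an array of 22575 spots, with 12 samples in Cy3 and 12 in Cy5. The files do not pair spots with genes, so spots are given by their number and their place on the array grid, with at most 2 per direction in a comparison, and no gene list was tested. Levels are normalised log2 signals from which the fitted dye and RIL terms were removed, given as mean ± SD. The labels do not say that replicates came from separate flies or cultures, so the p-values measure only the spread between these samples, which may be technical.

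The signal above local background depended on the dye. Its median over spots lay between 102 and 148 in the Cy3 samples and between 16.1 and 62.9 in the Cy5 samples, beside median backgrounds of 47.3 to 65.7. The net signal was below the local background at 49.8% to 93.8% of spots in Cy5 and at no more than 0.633% in Cy3. The median of all normalised values was 6.28, and the size of a difference from a level near it depends on the background correction and its offset. Such differences are given on the log2 scale, not as folds. Counts of spots beyond 2-fold were not restricted to spots away from that level and share this dependence. The number of arrays limits the precision further, since the 24 samples shared 12 arrays.

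After normalisation the samples were parted first by dye and array, then by tissue. The correlation between the 2 channels of an array, across spots, was 0.566 to 0.692 on 8 arrays and 0.831 to 0.941 on the other 4. Dye and this division of the arrays into a set of 8 and a set of 4 accounted for 99.8% of the first principal component, which held 50.9% of the variance. Tissue accounted for 96.8% of the second component, which held 15.9%. Across the brighter spots, replicates of the same dye and array set correlated at 0.923 to 0.964 over 11 pairs, and the 25 other replicate pairs at 0.494 to 0.924. These correlations are across spots, which are not independent replicates. Because the division was seen only in the data, each count of called spots in a comparison is also given with a separate dye effect for each array set, a fit chosen after the data were examined.

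**Figure D1:**
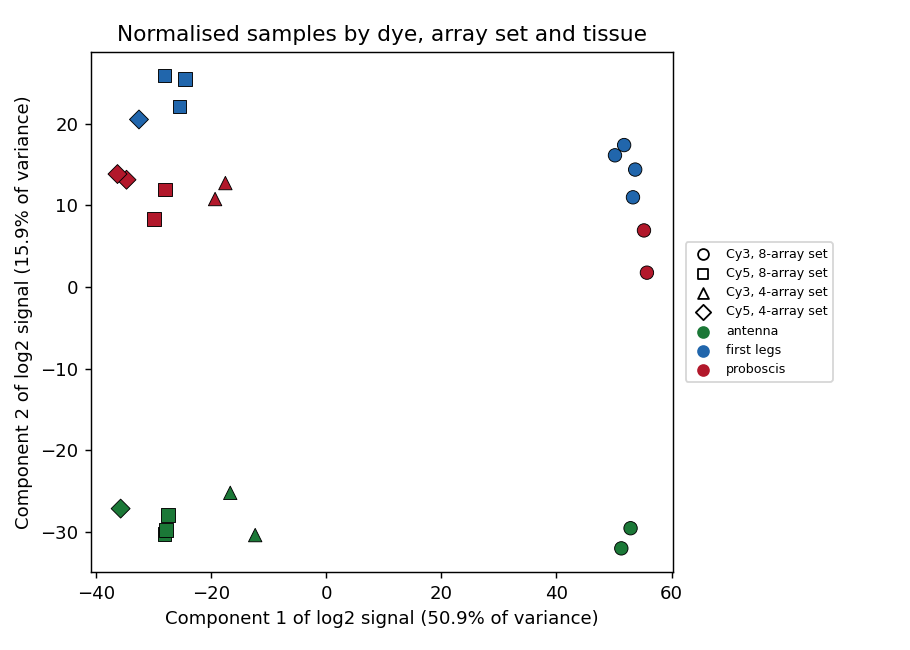
Scores of the 24 normalised samples on the first component (50.9% of variance, horizontal axis) and the second component (15.9%, vertical axis) of the log2 signal. Colours give the tissue and shapes give the dye and array set; the 8 Cy3 samples of the 8-array set lie apart from the other 16 along the horizontal axis, and antenna samples lie below the other tissues.

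Among the spots higher in the antenna than in both other tissues, spot 13930 (row 65, column 170) had a level of 12.63 ± 0.25 in female and 12.81 ± 0.28 in male antennae (SD, n = 4 each), against 6.47 to 6.64 in the other groups. It was higher than in the first legs by 5.83 ± 0.17 (5.30 to 6.25 over other settings) and than in the proboscis by 5.80 ± 0.15 (SE) on the log2 scale. Spot 20442 (row 96, column 17) was higher by 5.47 ± 0.14 (4.82 to 5.82 over other settings) and 5.49 ± 0.13 (SE), at 11.93 ± 0.24 in female antennae (SD, n = 4). In all, 1156 spots were higher in the antenna than in both other tissues at an adjusted p under 0.05 in limma, and the 12 with the largest differences exceeded the nearer tissue by 3.40 to 5.80 on the log2 scale.

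In the first legs, 522 spots were higher than in both other tissues. Spot 8915 (row 42, column 100) reached 10.78 ± 0.49 in females and 10.96 ± 0.26 in males (SD, n = 4 each) and lay between 6.20 and 6.37 in the other groups. On the log2 scale the antenna differed from the legs by -4.58 ± 0.12 (SE), and the legs from the proboscis by 4.70 ± 0.11 (SE; 4.02 to 5.12 over other settings). Spot 9030 (row 42, column 215) stood at 10.50 ± 0.75 in females and 11.02 ± 0.51 in males (SD, n = 4 each), and the same differences were -3.66 ± 0.21 (SE) and 3.64 ± 0.21 (SE; 3.23 to 3.86 over other settings). The 12 leading spots exceeded the nearer tissue by 2.72 to 4.58 on the log2 scale.

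In the proboscis, 630 spots were higher than in both other tissues. Spot 6078 (row 29, column 58) had a level of 13.21 ± 0.36 in females and 12.98 ± 0.09 in males (SD, n = 4 each). On the log2 scale the antenna differed from the proboscis by -5.02 ± 0.19 (SE; -5.15 to -4.23 over other settings) and the first legs by -3.40 ± 0.22 (SE). In the legs it still stood at 9.62 ± 0.25 in females (SD, n = 4), and the antenna differed from them by -1.62 ± 0.22 (SE). At spot 14508 (row 68, column 103) the antenna and the first legs differed from the proboscis by -4.02 ± 0.21 and -3.22 ± 0.23 (SE). The 12 leading spots exceeded the nearer tissue by 2.06 to 3.40 on the log2 scale.

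**Figure D2:**
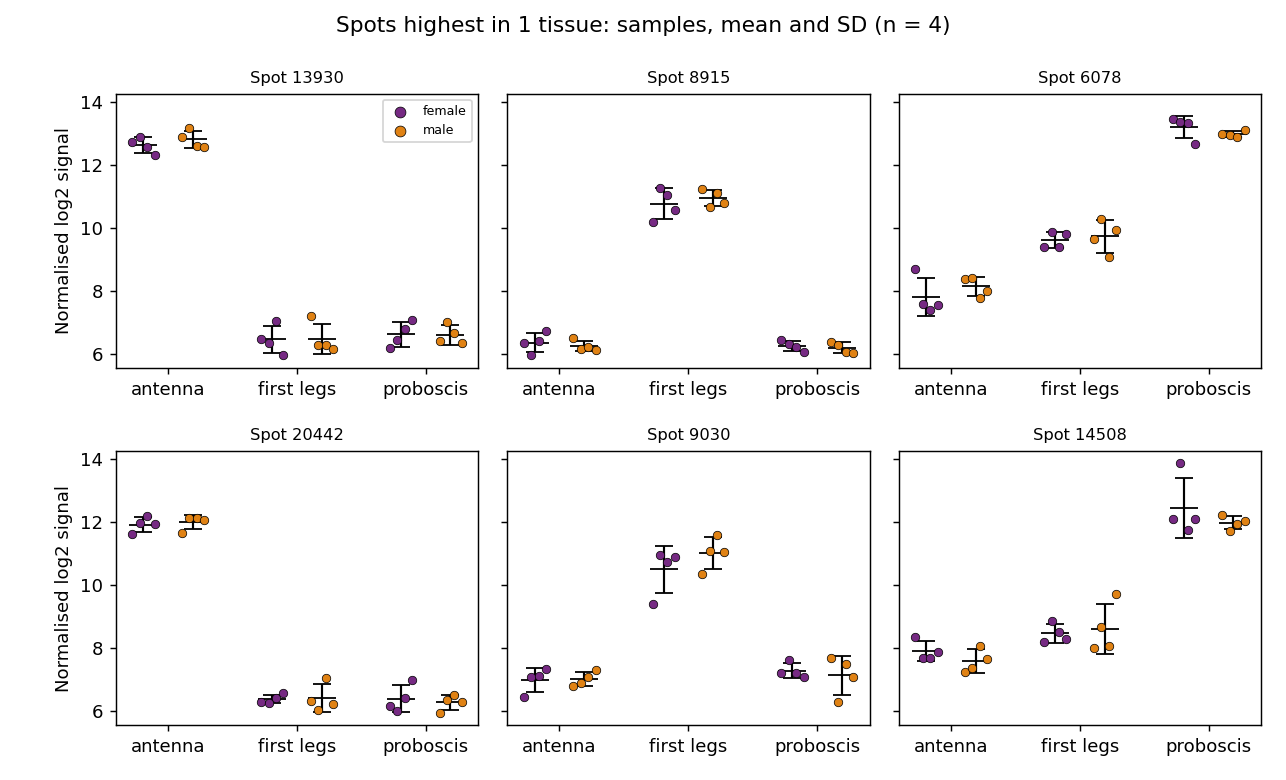
Normalised log2 signal (vertical axis) of the 6 named tissue spots in each of the 24 samples, by tissue (horizontal axis) and sex (colour). Points are samples and bars give the mean and SD of 4 samples; the upper row holds 1 spot for each tissue, with spot 13930 near 12.6 to 12.8 in the antenna and near 6.5 in the first legs.

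Pairwise, the antenna differed from the first legs at 2603 spots, of which 1624 were higher and 979 lower in the antenna, with 221 and 217 of them beyond 2-fold in the planned fit. It differed from the proboscis at 3087 spots, 1730 higher and 1357 lower, but at 1443 higher and 1562 lower when each sample was scaled to 1 median. The first legs differed from the proboscis at 1892 spots, 815 higher and 1077 lower. With a separate dye effect for each array set the 3 counts were 2783, 3588 and 2243, and 2222, 2921 and 1685 spots passed in both fits. That fit gave 1113, 751 and 692 spots higher in the antenna, first legs and proboscis than in both other tissues, of which 1017, 498 and 576 were the same spots. In it the antenna was higher at 1464 and lower at 1319 spots against the first legs, with 188 and 281 beyond 2-fold, and higher at 1917 and lower at 1671 against the proboscis. The first legs were higher at 1124 and lower at 1119 spots against the proboscis, so the excess of lower spots in the planned fit was absent.

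Male and female first legs differed most at 4 spots, whose log2 sex differences in the other tissues lay between -0.12 and 0.10. Spot 1777 (row 9, column 57) was higher in male legs by 1.76 ± 0.13 on the log2 scale (SE; 1.35 to 1.99 over other settings), at 8.35 ± 0.18 against 6.55 ± 0.26 in females (SD, n = 4 each). Spot 18813 (row 88, column 108) was higher by 1.75 ± 0.13 (SE; 1.37 to 1.97). Spot 321 (row 2, column 106) was lower in male legs, at 6.97 ± 0.53 against 8.83 ± 0.42 in females (SD, n = 4 each), a log2 difference of -1.81 ± 0.15 (SE). Spot 17374 (row 81, column 174) had a difference of -1.79 ± 0.12 (SE). By the rule that picked them, the 4 male and 4 female values did not overlap at any of these spots, and the limma adjusted p was between 1.24e-07 and 6.04e-07.

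In all, 27 spots differed between the sexes in the first legs, 25 higher and 2 lower in males. The count was 39, with 34 higher and 5 lower, with a separate dye effect for each array set, and 25 spots passed in both fits. The first count was 13 without female replicate 4 and 13 without male replicate 3, and the second was 8, 16 and 59 without female replicate 4, male replicate 3 and female replicate 2. The planned fit to the 8 leg samples alone was not obtained, because the proboscis samples were fitted in its place. The split of higher and lower spots was 21 and 5 with cyclic loess and 18 and 4 with loess within arrays.

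In the antenna, 25 spots differed between the sexes, 24 higher and 1 lower in males. Sex was nearly confounded with array set here. The 4-array set held 2 female samples in Cy3 and 1 in Cy5. The 8-array set held 1 female sample in Cy3 and all the males, 1 in Cy3 and 3 in Cy5. The planned fit had no term for array set. Spot 11956 (row 56, column 131) was higher by 1.43 ± 0.12 on the log2 scale (SE; 1.07 to 1.67 over other settings), at 7.98 ± 0.35 in male and 6.46 ± 0.17 in female antennae (SD, n = 4 each), with an adjusted p of 4.95e-06 in limma, and its call was lost in 1 of 20 other settings. Spot 3474 (row 17, column 34) was higher in males by 1.18 ± 0.15 (SE; 0.89 to 1.37), and its call was lost in 4 of 20, with a limma adjusted p of up to 0.196. The single spot lower in males was 14302 (row 67, column 112), at 7.36 ± 0.14 against 8.41 ± 0.39 in females (SD, n = 4 each), a log2 difference of -0.93 ± 0.16 (SE; -1.10 to -0.52 over other settings), and its call was lost in 6 of 20, with a limma adjusted p of up to 0.866. It was also lost without antenna female replicate 3, antenna male replicate 4 or proboscis female replicate 3 or 4 (limma adjusted p up to 0.0789). With a separate dye effect for each array set it was lost in 9 of 24 such fits (up to 0.232), without antenna female replicate 3, antenna male replicate 1, 3 or 4, leg female replicate 3, leg male replicate 3 or proboscis female replicate 2, 3 or 4. With a separate dye effect for each array set 33 spots differed, 29 higher and 4 lower, and 19 passed in both fits. That count was 21 without female replicate 3. In limma, 4 spots passed when each sample was scaled to 1 median. The planned fit to the 8 antenna samples alone was not obtained either. The split of higher and lower spots was 10 and 2 with cyclic loess and 14 and 3 with loess within arrays. The split turned in the 8-array set alone, which held 1 female sample, with 10 higher and 34 lower in males.

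The antenna and the first legs shared male-higher spots. Of the 24 male-higher spots of the antenna and the 25 of the first legs, 13 were the same, where independent lists would share 0.0266. Spot 11956 was one of them, with a log2 difference of 1.11 in the first legs, and so was spot 3474, with 0.84. Over the 13 spots the log2 difference ran from 0.44 to 1.43 in the antenna and from 0.32 to 1.11 in the first legs. With a separate dye effect for each array set the lists shared 17 of 29 and 34 spots.

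**Figure D3:**
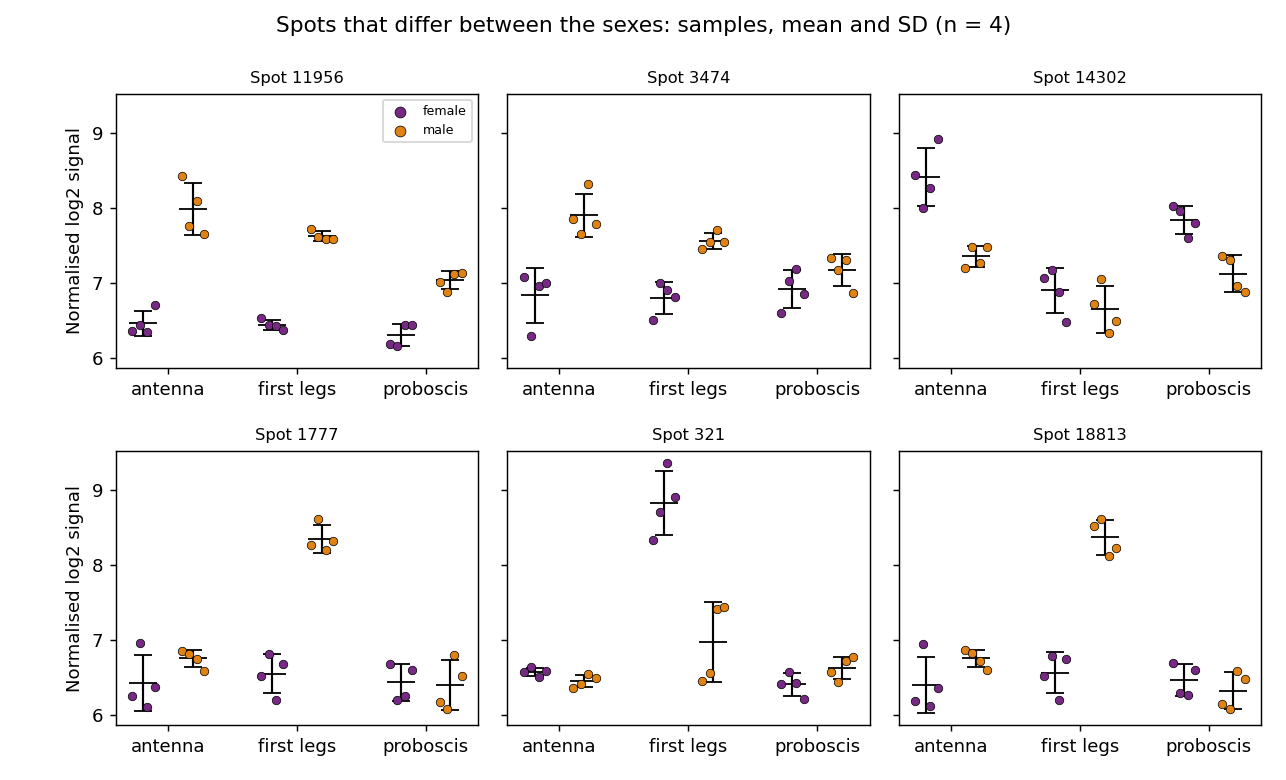
Normalised log2 signal (vertical axis) of 6 named sex spots in each of the 24 samples, by tissue (horizontal axis) and sex (colour). Points are samples and bars give the mean and SD of 4 samples; spot 1777 stands at 8.35 in male legs and between 6.40 and 6.75 elsewhere, and spot 11956 is higher in males than in females in each tissue.

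In the proboscis, the number of sex differences depended on how the dye was fitted. The planned fit called 1219 spots, 702 higher and 517 lower in males, but a separate dye effect for each array set left 3, and all 3 were lower in males. Fitted alone, the 8-array set gave 4 spots and the 4-array set 0 in limma, with 1528 at an unadjusted p under 0.05 in the latter. The 8-array set held 2 female samples in Cy5 and 2 male samples in Cy3, and the 4-array set 2 female samples in Cy3 and 2 male samples in Cy5. In the 4-array set the dye effect could be estimated only from 1 Cy5 sample of female antennae beside 2 in Cy3. The fit to that set had no array block and 4 samples of each dye, against 8 of each dye and a block in the 8-array set. The 2 fits therefore differ in power, and their counts are not alike. Spot 5784 (row 27, column 194) was lower in males in both fits, at 6.22 ± 0.15 against 7.13 ± 0.16 in females (SD, n = 4 each), with a log2 difference of -0.85 ± 0.07 (SE) and, with a separate dye effect for each set, -0.96 ± 0.12 (SE) and a limma adjusted p of 0.00323. Spot 2572 (row 12, column 207) differed by -1.07 ± 0.10 (SE) and by -1.03 ± 0.15 (SE), with an adjusted p of 0.0362 in the second fit. These spots were chosen after their values were seen. The count of 3 was 1 without any of 13 samples, namely antenna female replicate 1, antenna male replicates 2 and 3, leg female replicates 1, 2 and 4, all 4 leg male replicates, proboscis female replicate 4 and proboscis male replicates 3 and 4.

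The spots that the planned rule named in the proboscis did not pass in the fit with a separate dye effect for each array set. Spots 12071 (row 57, column 31) and 12218 (row 57, column 178) were higher in males by 2.56 ± 0.54 and 2.55 ± 0.56 (SE) on the log2 scale in the planned fit and by 0.14 ± 0.17 and 0.01 ± 0.15 (SE) with a separate dye effect for each array set. Spots 3238 (row 16, column 13) and 7342 (row 35, column 32) differed by -1.29 ± 0.21 and -1.28 ± 0.19 (SE), then by -0.72 ± 0.30 and -0.70 ± 0.22 (SE). The planned count of 1219 was 13 without female replicate 2, 41 without female replicate 3, 808 without female replicate 4, 750.0 without male replicate 1, 792 without male replicate 2, 660.0 without male replicate 4 and 1849 without leg male replicate 2. Cyclic loess left 89 spots, 23 higher and 66 lower in males.

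The sex difference itself differed between tissues at 27 spots in a joint test. The 4 spots of the first legs led this list, with limma adjusted p-values from 6.11e-06 to 1.84e-05, and in the antenna and proboscis their log2 differences lay between -0.12 and 0.10. With a separate dye effect for each array set 8 spots passed, 6 of them the same, and the adjusted p-values of the 4 leg spots ran from 4.29e-07 to 0.00136. Of the 13 spots shared by antenna and first legs, 2 passed this test in the planned fit and 0 in the second, limma giving 1182 spots at an unadjusted p under 0.05 there. The count of 27 was 814 without proboscis female replicate 1, 11 and 17 without proboscis male replicates 4 and 1, 17 and 70.0 without antenna female replicate 2 and antenna male replicate 4, and 72, 42 and 14 without leg female replicate 2, leg male replicate 3 and leg male replicate 4. The count of 8 was 5 without antenna female replicate 2, leg female replicate 4, leg male replicate 3 or 4, or proboscis male replicate 3 or 4, and 13 without antenna male replicate 4.

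The descriptions label each sample RIL 58 or RIL 89, with 12 samples each and 2 of each in every group, while the series text names a single isogenic line, WI89. Between the RIL numbers limma called 0 spots, with 949 at an unadjusted p under 0.05, and 0 with a separate dye effect for each array set, with 1405. The latter count was 1 without proboscis male replicate 2. The sexes differed in this respect. In females, whose replicates 1 and 2 are all labelled RIL 58 and replicates 3 and 4 RIL 89, 54 spots differed between the numbers in a fit with a term for each sex. In males the RIL numbers do not follow the replicate numbers, and 0 spots differed between them, with 1443 at an unadjusted p under 0.05, but 34 differed between replicates 1 and 2 and replicates 3 and 4.

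Over all 24 samples, 206 spots differed between replicates 1 and 2 and replicates 3 and 4, 95 higher and 111 lower in the latter, with a separate dye effect for each array set. Spot 10228 (row 48, column 123) was higher in replicates 3 and 4 by 2.40 ± 0.16 (SE) and spot 11142 (row 52, column 177) by 2.34 ± 0.22 (SE) on the log2 scale. Spots 1849 (row 9, column 129) and 18885 (row 88, column 180) differed by -1.84 ± 0.16 and -1.77 ± 0.14 (SE). At each of the 4 spots all 24 samples lay on the side of their replicate numbers, and the limma adjusted p was between 1.82e-07 and 5.47e-06. The count was 116 with the RIL number as a further term, and 39 with 1 dye effect for all arrays. This comparison was chosen after the data were examined.

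**Figure D4:**
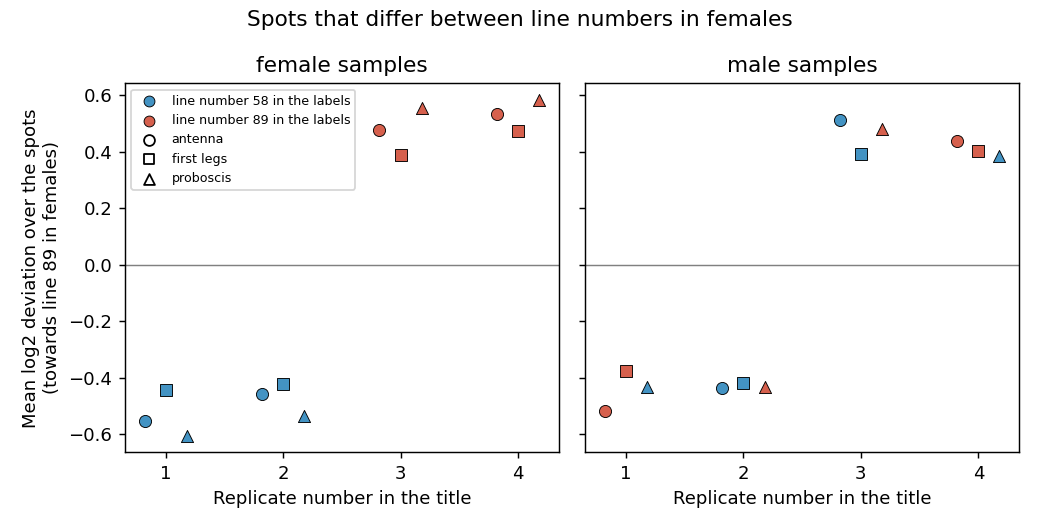
Mean log2 deviation of each sample from its group and dye level over the 54 spots that differed between RIL 58 and RIL 89 in females, turned so that RIL 89 of the females is positive (vertical axis), by replicate number (horizontal axis). Colours give the labelled RIL number (line number in the plot) and shapes the tissue; replicates 3 and 4 of males lie between 0.384 and 0.513 and replicates 1 and 2 between -0.516 and -0.377, whichever RIL number they carry.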

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

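The tests with array sets or separate dye effects and of the spots shared by antenna and first legs were chosen after the results were seen; the tests of left-out samples, sex labels, tissue labels and the interaction were planned.

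At 4 of 50 groups of 4 samples examined, 1 sample stood far from the other 3, and chance gives about 1 in 20 groups. At spot 3474, antenna female replicate 2 had a level of 6.29 against 6.96 to 7.08, a gap of 0.851 of the group's range. At spot 20442, antenna male replicate 1 had 11.65 against 12.08 to 12.14, a gap of 0.88. At spot 9030, leg female replicate 1 had 9.39 against 10.75 to 10.96, a gap of 0.864. At spot 6078, proboscis female replicate 4 had 12.68 against 13.33 to 13.46, a gap of 0.831. With a separate dye effect for each array set these gaps were 0.458, 0.449, 0.86 and 0.493 in turn, so 3 of the 4 samples no longer stood apart.

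The sex difference differed between tissues at the 4 spots of the first legs, with limma adjusted p-values of 6.11e-06 at spot 17374, 1.84e-05 at spot 321, 6.11e-06 at spot 18813 and 8.75e-06 at spot 1777. In each, all 4 male legs lay on the same side of all 4 female legs, as the rule that picked these spots required.

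The 1219 sex calls in the proboscis may come from a dye effect that differs between the array sets, since 3 of them stayed called with a separate dye effect for each set. Their median log2 difference in the direction of the call was 0.83 in the planned fit and 0.14 with separate dye effects, while their median SE fell from 0.205 to 0.129. As a set, the called spots thus lost most of their difference. The SE fell at spots 12071 (0.538 to 0.173) and 12218 (0.561 to 0.147) but rose at spots 3238 (0.205 to 0.297) and 7342 (0.191 to 0.215). Lost precision may therefore have ended some of the calls. A sex difference of the size first fitted is argued against by the 8-array set fitted alone, whose median was 0.15 (quartiles 0.04 and 0.28). In the 4-array set alone the median was 0.12 (quartiles -0.02 and 0.26). That value decides less, because the dye effect there rested on 1 Cy5 antenna sample beside 2 in Cy3. A smaller sex difference of these spots stays open, as the direction of each call was taken from the same samples. None of the other 34 splits of the 8 samples gave over 13 spots, those by dye and by array set included, which argues against a chance division. However, only the real split follows dye in opposite directions in the array sets, so the splits do not part sex from that dye pattern.

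Of the 13 male-higher spots shared by antenna and first legs, 12 passed in both tissues with a separate dye effect for each array set, which argues against the unequal spread of dyes and sets over the sexes as their whole cause, although 5 of 13 passed in both in the 8-array set alone, with 1 antenna female sample, where all 13 were higher in males in both. With separate dye effects all 13 were also higher in males in the proboscis, by a median of 0.42, as they were in each set alone, although 0 passed there in limma (723 spots had an unadjusted p under 0.05), so a male-higher signal common to the 3 tissues is a candidate explanation. All 4 spots of the first legs, which form near-identical pairs (r of 0.992 and 0.995 across samples), passed with separate dye effects (limma adjusted p up to 1.27e-05, log2 differences of 1.67, 1.67, -1.78 and -1.76). In the legs both sexes were spread evenly over the dyes, and only 1 sample, a female one in Cy5, lay in the 4-array set. A dye effect could therefore hardly part the sexes there, and this fit adds little to what the layout already shows about dye. The lowest share of a difference left without any 1 leg sample was 0.9, and all 32 such fits passed, so no single leg sample carried these differences. The rule that picked the spots, with male and female values that do not overlap in the same samples, favoured this outcome. Chance could not be excluded for the number of calls, as 2 of 35 splits gave as many in the antenna (25, highest other 39, a split that follows the replicate numbers; 25 with those numbers as a term) and 2 of 35 in the first legs (27, highest other 34).

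In each tissue comparison, 1 of 100 shuffles of tissue labels, the real one, gave as many spots. This argues against chance in the fit with 1 dye effect for all arrays. The real values and the highest others were 2603 and 1803 for antenna against first legs, 3087 and 2206 for antenna against proboscis, and 1892 and 997 for first legs against proboscis. They were 1156 and 2, 522 and 111, and 630.0 and 428 for spots higher in the antenna, first legs and proboscis than in both other tissues. For the interaction, 3 of 100 shuffles of the sex labels, the real labels included, gave as many as 27 spots. The highest other gave 768, which points to a structure of the samples, whose source was not tested. All these shuffles were run with 1 dye effect for all arrays and without regard to dye, array set or shared array. The sexes were spread unevenly over dyes and array sets, and the tissues over array sets. No shuffle was run with a separate dye effect for each array set. The shuffles therefore do not decide whether chance gave the interaction calls, and they do not test the tissue counts of that fit.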

How the results depend on the processing

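The fits with array sets, with loess within arrays and with the replicate numbers in place of the line number were chosen after the data were examined. The 4 leg spots kept direction and call in each setting in which they were tested singly, 1 sample left out included. So did the 6 tissue spots, in the 1 contrast each in which they were followed. The contrast of a tissue spot with the other tissue was not followed over settings. Fits to the 8 samples of the antenna alone and of the first legs alone were not obtained. In the antenna, first legs and proboscis in turn, the sex counts were 5, 6 and 3 without the dye term and 3, 7 and 6 with no array block. With the array as a fixed block they were 0 (1641 at an unadjusted p under 0.05 in limma), 5 and 0 (4127). The proboscis count was 0 in a fit to its own 8 samples (1114). Median scaling gave 4 in the antenna, and cyclic loess 12 in the antenna and 89 in the proboscis. Quality weights gave 3459 in the proboscis, a separate dye effect for each set 3, also with the replicate numbers for the line number, loess with that dye effect 0 (592), the 8-array set 4 and the 4-array set 0 (1528); the 8-array set gave 44 in the antenna, 10 higher and 34 lower in males, from 1 female sample. The interaction count was 6 with median scaling, cyclic loess or no dye term, 446 without the dimmest spots, 54 without the variance trend, 1126 with quality weights, 3 with the array as a fixed block, 7 with none, 8 with a separate dye effect, also with the replicate numbers for the line number, 16 with loess within arrays and 7 with both. Without the dye term the tissue counts were 1551, 1556 and 893 and the tissue-enriched counts 684, 338 and 264; with the array as a fixed block antenna against legs gave 1382, legs against proboscis 983, and the enriched counts were 693, 289 and 344. No array block gave 1845 and 1204 against the proboscis and 333 enriched there, and median scaling gave 770.0 enriched in the antenna. Quality weights gave 4850.0 between legs and proboscis and 972 and 1099 enriched in them. The 8-array set gave 1384 for antenna against legs, 1647 for antenna against proboscis and 604 enriched in the antenna. Spot 12071 turned to -0.12 in the 4-array set, and spots 12071 and 12218 to -0.41 and -0.34 with loess and separate dye effects; apart from fewer samples in the subsets, the cause was not tested.

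With 1 sample left out, over both dye models, the sex counts ran from 18 to 44, 8 to 59 and 1 to 1849, the tissue counts from 1786 to 2927, 2554 to 3856 and 1271 to 2439, the interaction from 5 to 814, the line number from 0 to 1, and the enriched counts from 846 to 1275, 408 to 792 and 429 to 756. Spot 12071 ran from -0.0647 to 2.97 and spot 12218 from -0.0570 to 2.97. With the replicate number as a block the interaction gave 50, and 7 with separate dye effects, where the proboscis gave 1; the other sex counts were 25, 28 and 1430.0. Same-number samples were not treated as paired in the planned fit. Deviations were correlated over 0.1 in 21 of 60 same-number pairs, and in 31 of 60 once dye, array set and line number were removed (median 0.104, against -0.0412 for other pairs). The latter values point to some variation shared by replicate number, which the planned fit leaves out and the fits with the replicate number as a block take up. Gene lists and gene means were not run, as the files do not pair spots with genes. Dim Cy5 signal limits what can be detected.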

Other observations

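The tests of the replicate numbers, of line numbers within each sex and of repeated signals were chosen after the data were examined; only the shuffles of line numbers over all samples were planned.

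The 206 spots that part replicates 1 and 2 from replicates 3 and 4 may reflect line numbers that 6 male samples do not carry, or a batch of hybridisation. Line numbers as labelled in both sexes are argued against by the 54 spots that differed between the numbers in females, whose median difference in that direction was 0.89 in females and -0.00142 between line numbers in males. Between replicates 1 and 2 and replicates 3 and 4 of the males it was 0.668, and 20 of the 54 were called there in the same direction. The 2 explanations cannot be told apart, because on 12 of 12 arrays both samples lay on the same side of this division. In the fit with a separate dye effect for each array set, 1 of 100 splits, the real one, gave 206 spots and the highest other 1. The splits were drawn without regard to arrays, whereas the real division keeps both samples of each array together. They therefore do not show how often a division between arrays gives as many spots. The division and the fit were also chosen after the data were examined. With 1 dye effect for all arrays the count was 39, and 1 shuffle of line numbers in such a fit gave 486.

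For the labelled line numbers shuffles decide nothing about chance, since limma called 0 spots (949 at an unadjusted p under 0.05) and all 100 shuffles had to give as many; the highest other gave 486. In that shuffle 14 of 24 samples lay on the side of the replicate numbers.

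Some spots carried nearly the same values across the samples. Of 449 bright and variable spots, 63 had a partner with a correlation over 0.99, and for 51 of these the partner lay 16967 to 17070 spot numbers away; a slightly wider window, set after these distances were seen, holds 0.44% of all pairs of spots. Spots 1777 and 18813, spots 321 and 17374, and spots 1849 and 18885 lie within these distances. The files do not say whether such spots carry the same probe, so the counts are of spots and not of transcripts.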
